A study of Mus musculus with 12 samples.

How the data were processed

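RNA of 12 cultures of primary mouse granulosa cells was measured on Illumina Sentrix Mouse-6 arrays with Cy3 labelling, after T7 amplification of 100 ng of RNA per the labels. The cultures had received PBS, activin A or activin A plus follistatin for 24 h, with 4 arrays per treatment. The deposited values are on a log2 or log2-like scale: they run from 6.75 to 16.2 on every array together, with nearly equal medians. The authors had normalized them between arrays by a method that the files do not state, and sorted columns differed from their mean by up to 0.183. The submitters' notes name lumi version 1.2.0 without its role, and whether the scale is plain log2 or a variance-stabilizing transform close to it is not stated. The values were used as deposited, and fold changes read the scale as plain log2. The files hold no detection calls and show no background subtraction, so log2 differences are differences on the deposited scale and understate changes near background. The correlation between arrays was 0.967 to 0.994. Of the 46116 probes in the table, 32 control spots were left out and 46084 were tested. The highest mean of a control spot, 7.31, was taken as background. The number of arrays limits the precision.

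The table has no gene names. A probe was named where its identifier holds a RefSeq accession (9 probes) or a zero-padded number that is an Entrez gene number in the reference table of mouse genes on assembly GRCm38.p6 (9832 probes). The files do not say that these numbers are Entrez gene numbers, so this was tested. Of 11897 such numbers 82.6% were in the table, against 46.0%, 44.6% and 41.5% after adding 1, 2 and 5 to each, and 11.3% of unpadded numbers with 5 digits. Probes so named for ribosomal proteins (83 probes) had a median of 14.5, those for proteasome subunits (21 probes) 10.3 and those for olfactory receptors (343 probes) 7.09, and 0 of 10000 permutations of the names gave a ribosomal median as high. The mean signals of a pair of probes with 1 number had a Spearman rho of 0.322 across numbers, so probes of 1 gene can read differently. Named were 9841 probes (21.4% of those tested) of 8131 genes, 1504 of them with more than 1 probe, and the probe with the highest mean over all arrays stood for the gene. The other 36243 probes were tested and counted without a name.

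Groups were taken from the labels. Comparisons were made with limma 3.58.1 in R 4.3.3, with 1 fit of 3 group means over the 12 arrays and moderated statistics, 2-sided, with Benjamini-Hochberg adjustment over all 46084 probes and a threshold of 0.05. The 4 experiments share numbers across the treatments, which the values were used to check over the 14707 probes above background. After group means were removed, arrays with the same number had r of 0.331 to 0.801 and other pairs -0.632 to 0.406, and 11 of 12 arrays correlated best with their own number in both other groups. Experiment accounted for 31.7% of the summed variance of these probes, treatment for 55.5% and the rest was 12.8%. Probes with a large variance weigh most in these sums. The median share of a probe's own variance was 29.7% for experiment and 28.3% for treatment. The fit without a block was chosen before the data were examined, as were the alternatives, the gene lists and the anchor genes, and the fit with experiment as a block is printed beside it because it changes the counts.

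Genes named in the text were taken, for each comparison, from the 8 with the largest rise and the 8 with the largest fall among those called with the same direction in all 4 experiments, the anchor genes with a named probe, and up to 4 members of a described list with the smallest p. The 30 fixed lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, each with Benjamini-Hochberg adjustment over the lists. Lists with fewer than 5 measured members were only counted. The share of the activin change left with follistatin was measured in an experiment left out of the selection of probes. The overlap of 2 comparisons was set beside that of independent lists, and the correlation and covariance of their differences beside those of 50 simulated data sets with unchanged groups.

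The fits were tested on simulated data. Without a block, limma recovered 73.1%, 95.5% and 98.5% of probes shifted by 0.5, 1 and 2 on the log2 scale with 0 false calls, and with the block 85.1%, 98.5% and 100% with 7 false calls. A simulated share of -0.4 was estimated at -0.397 and a share of 0 at 0.003, and of the simulated lists the 1 shifted list and 0 of 30 unchanged lists were called. The simulated lists were drawn at random, with independent noise per gene. Their result does not cover lists whose members vary together, such as the cell-cycle list, with an estimated correlation of 0.243. Alternatives were the block (fixed or random, with a consensus correlation within experiments of 0.0791), quantile normalization, median centring, filters on dim probes, array weights, a variance trend, only the 8 arrays compared, other thresholds, the mean of a gene's probes, and leaving out each array or experiment. Tables were made with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.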

Results

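Granulosa cells are the hormone-producing support cells that surround the egg in an ovarian follicle. Activin A is a growth factor of the transforming growth factor beta family, and follistatin is a secreted protein that binds it and blocks its action. Primary granulosa cells of immature mice aged 21 to 23 days, each culture drawn from a pool of 14 to 20 ovaries, received PBS as vehicle, activin A, or activin A together with follistatin for 24 h. The experiment was done 4 times, which gave 12 microarrays with 4 per treatment, and each experiment supplied 1 array of each treatment. Values are signals on a log2-like scale between 6.75 and 16.2, and the highest mean of the control spots, 7.31, served as the background level. Of the 46084 probes tested, 31.9% had a mean above it. Genes were named from the numbers in the probe identifiers, a reading that the files do not state and that was tested on the data, so 8131 genes carry a name here and 36243 probes do not. Differences are given as log2 differences with their standard error (SE) from 4 arrays per group. Fold changes read the scale as plain log2. Because background was not subtracted, differences of genes near 7.31 understate the change.

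The comparison of activin with PBS asks which transcripts activin changes in granulosa cells. Activin raised the mRNA of its own antagonist most among the named genes: Fst, which encodes follistatin, rose by 2.52 ± 0.19 (SE), a 5.72-fold change (adjusted p = 3.13e-05, limma with Benjamini-Hochberg adjustment). Chst8, a sulfotransferase that modifies sugar chains of glycoproteins, rose by 2.02 ± 0.12, and Igf1, which encodes a growth factor for the follicle, rose by 1.25 ± 0.16. In the other direction, Col8a1, which encodes a chain of type VIII collagen, fell by 2.94 ± 0.10 and Gstm1, a glutathione transferase, fell by 2.74 ± 0.23. Gstm1 has 2 named probes, and the one with the lower mean signal was not called. Aldh1a1, which makes retinoic acid from retinaldehyde, fell by 1.83 ± 0.22 from one of the higher levels on the array, 14.5 with PBS.

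**Figure D1:**
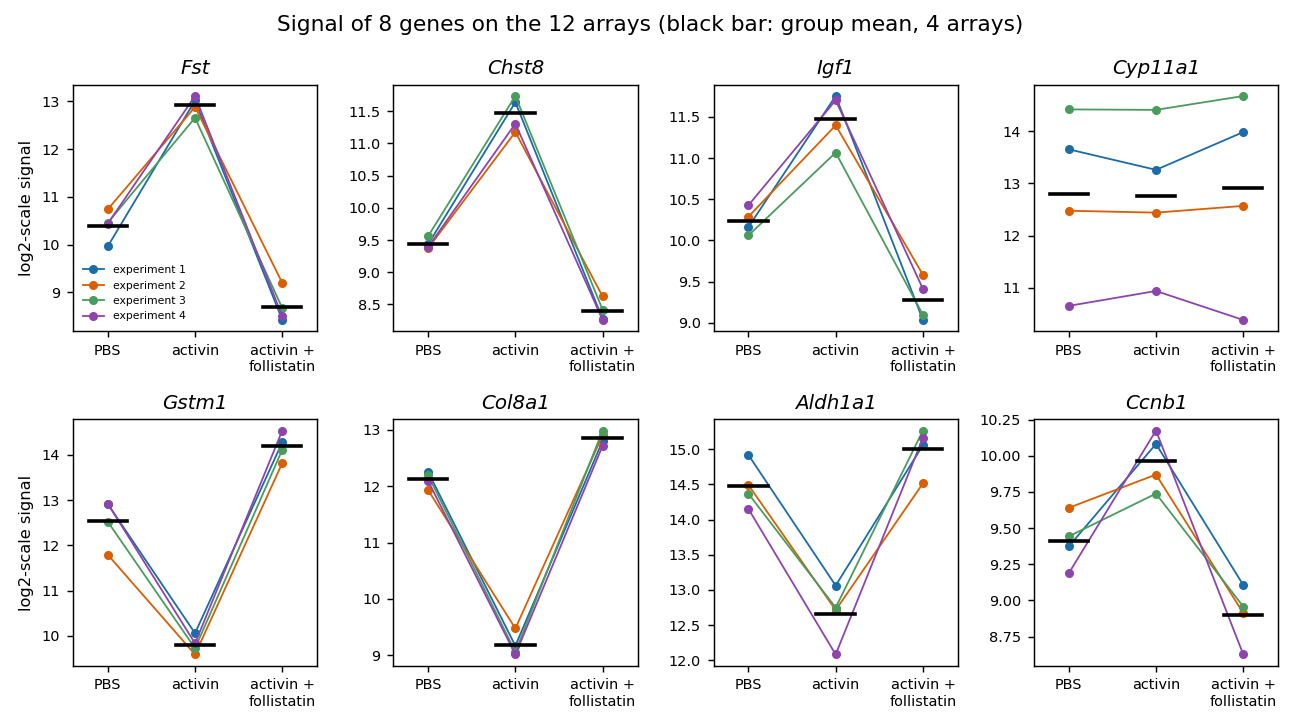
Log2-scale signal (y axis) of 8 genes in the 3 treatments (x axis); points are single arrays, lines join the arrays of 1 experiment and black bars are means of 4 arrays. Fst, Chst8, Igf1 and Ccnb1 lay highest with activin and lowest with follistatin added, Gstm1, Col8a1 and Aldh1a1 the other way round, and Cyp11a1 differed between experiments (10.4 to 14.7) far more than between treatments.

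The other largest rises among named genes were Cables1 (2.11 ± 0.43), a protein that binds cyclin-dependent kinases, Fam13a (2.03 ± 0.15), Loxl1 (1.65 ± 0.19), a lysyl oxidase that acts on elastic fibres, Socs2 (1.58 ± 0.23), an inhibitor of growth hormone and cytokine signalling, Tmem45a (2.84-fold, SE 0.24 in log2) and the endocytic adaptor Sh3kbp1 (1.40 ± 0.09). The other largest falls were Cntnap2 (4.01-fold lower, SE 0.21 in log2), a cell adhesion protein of the neurexin family, the caveolae protein Cav1 (-1.99 ± 0.25), Gxylt2 (-1.75 ± 0.21), a xylosyltransferase, Gask1b (-1.66 ± 0.30) and Pcp4l1 (-1.64 ± 0.33). The 16 largest changes were picked among genes with the same direction in each of the 4 experiments, so that direction is no separate evidence. Activin changed 1342 of 46084 probes at an adjusted p below 0.05, 762 up and 580 down, and 406 of the 8131 named genes, 232 up and 174 down. With the experiment as a block the counts were 2820 probes and 863 genes.

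Among the fixed gene lists, the matrix genes moved both ways: 2 of 26 measured members rose, among them Loxl1, and 3 fell, the collagens Col3a1 (-0.73 ± 0.12) and Col5a1 (-0.69 ± 0.15) and the basement membrane proteoglycan Hspg2 (-0.80 ± 0.17). Adjusted over the list alone, 3 rose and 6 fell. Of 11 glutathione and antioxidant genes, Gstm1 and its paralog Gstm2 (-1.53 ± 0.23) fell and 1 rose; cross-hybridization between the Gstm paralogs was not excluded. Of 12 steroidogenesis genes, Hsd11b2 (1.11 ± 0.09), which inactivates glucocorticoids, and Cyp1b1 (0.92 ± 0.22), which hydroxylates estrogens, rose. With the block Scarb1, a lipoprotein receptor, was also called higher and Stard5, a lipid transfer protein, lower (-0.31 ± 0.15 without the block). Of 18 ovulation and luteinization genes, Rgs2 (0.93 ± 0.07), a regulator of G-protein signalling, and the transcription factor Cebpb (0.91 ± 0.17) rose, with 5 higher and 1 lower adjusted over the list alone, and 3 higher and 2 lower with the block. The chaperone Hspa5 rose by 1.07 ± 0.08 among 4 genes of the endoplasmic reticulum stress list, the cell-cycle inhibitor Cdkn1a by 0.94 ± 0.20 among 5 G1 regulators, and Timp2, an inhibitor of metalloproteinases, fell by 1.34 ± 0.14 among 14 proteases and inhibitors.

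Of 21 measured cell-cycle genes, Ccnb1 (0.56 ± 0.12), which encodes cyclin B1, and Cdc6 (0.39 ± 0.08), a DNA replication licensing factor, rose and none fell, and 10 rose when p was adjusted over the list alone. As a set these genes ranked above other genes with a preset correlation (limma camera, adjusted p = 9.51e-05), and the call was lost with an estimated correlation (adjusted p = 0.876). Fry, which asks whether the members of a list move one way on balance, did not pass for it (adjusted p = 0.0624) and passed for the granulosa list alone (5.10e-04). Of the 6 measured granulosa genes only Fst was called, and with the block 2 were higher and 1 lower. The mean of the granulosa list was 0.61 and its median 0.23. Camera did not call the granulosa list with the preset (adjusted p = 0.0846) or the estimated correlation (0.830). The ovulation and glycolysis lists were also called upward with the preset correlation (adjusted p = 0.0424 each) and lost with the estimated one (adjusted p = 0.898 each). Of the genes fixed as anchors, 5 had a named probe. Besides Fst these were Lhcgr, the luteinizing hormone receptor (0.04 ± 0.05), Esr1, an estrogen receptor (-0.01 ± 0.04), Star, which brings cholesterol into mitochondria (0.11 ± 0.08), and Cyp11a1, which cleaves the cholesterol side chain (-0.04 ± 1.05), and none of the 4 passed the test. The signals of Lhcgr and Esr1 were at background. The SE of Cyp11a1 includes differences between experiments: with the experiment as a block it was 0.15, and the gene was still not called.

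Markers of other ovarian cells were read in the same fit. Of 11 stromal and theca markers, Aldh1a1 and Col3a1 fell, and Dcn, a matrix proteoglycan, had a difference of -1.77 ± 0.54 that did not pass (adjusted p = 0.14) and passed with the experiment as a block. Gli2, near background, had 0.20 ± 0.10 and was called higher only with the block, and the median of the list was -0.02. The oocyte, macrophage, erythroid, smooth muscle, endothelial and surface epithelium lists held 0 genes called by limma, where the whole comparison had 5644 probes at an unadjusted p below 0.05, and with the block 1 endothelial and 2 surface epithelium genes were called lower. Among housekeeping genes, 1 of 14 was called, Actb, at -0.36 ± 0.08. For activin versus PBS, leaving out 1 array at a time gave 888 to 1356 probes, with the lowest count when the PBS array of experiment 3 was left out, and leaving out a whole experiment gave 625 to 994. Of the genes named for this comparison, some lost their call when 1 single array was left out, with adjusted p up to 0.131 (limma). This held for 9 of the 12 arrays for Cyp1b1 and for Actb, 8 for Ccnb1, 6 for Col5a1 and 5 for Hspg2 and Cdkn1a. It held for 4 arrays for Cdc6, 3 for Pcp4l1 and Cables1, and 1 for Cebpb. The calls of Tmem45a, Gask1b and Col3a1 were lost without at least 1 whole experiment.

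The comparison of activin plus follistatin with PBS asks what was left of the activin response when the antagonist was present. Of the 21 named genes that differed, 19 were called for activin alone as well, all on the other side of PBS, and with the experiment as a block 128 genes lay on the other side and 3 on the same side. Fst fell by 1.70 on the log2 scale relative to PBS (SE 0.19, adjusted p = 0.0028, limma with Benjamini-Hochberg adjustment), at 8.70 against 10.4, and the arrays read the mRNA of the cells, not the follistatin protein that was added. Chst8 (-1.05 ± 0.12), Igf1 (-0.95 ± 0.16) and Hsd11b2 (-0.85 ± 0.09), all raised by activin, were lower than with PBS. Gstm1 (1.65 ± 0.23) and Col8a1 (0.73 ± 0.10), both lowered by activin, were higher.

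The other largest falls were the sialyltransferase St3gal4 (-1.30 ± 0.09), the ceramide synthase Cers5 (-1.04 ± 0.10), the uridine-cytidine kinase Uck1 (-1.02 ± 0.11) and the tubulin Tuba8 (-1.02 ± 0.17). Other large rises were the secreted guidance ligand Slit2 (0.70 ± 0.12), the nuclear receptor Rorb (0.58 ± 0.06), the complement protease C1s1 (0.42 ± 0.07), the protocadherin Pcdh9 (0.38 ± 0.04) and the lysosomal enzyme Ppt1 (0.35 ± 0.04). These genes too were picked only with the same direction in each of the 4 experiments. Hsd11b2 was at background with follistatin added (7.25), so its difference is understated. In all, 82 probes passed, 29 up and 53 down, and 21 named genes, 9 up and 12 down. With the experiment as a block the counts were 557 probes and 176 genes.

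Of the fixed lists, none had more than 1 gene past the threshold. Of the 21 cell-cycle genes none passed over all probes, while 10 were lower when p was adjusted over the list alone, and at an unadjusted p below 0.05 the whole comparison held 3304 probes. Rrm2, a ribonucleotide reductase subunit, was at -0.42 ± 0.09, Tk1, a thymidine kinase, at -0.37 ± 0.09, Cdc6 at -0.39 ± 0.08 and Ccnb1 at -0.51 ± 0.12. As a set they ranked below other genes with the preset correlation (limma camera, adjusted p = 3.55e-13), not with an estimated correlation (adjusted p = 0.182). Fry passed for the cell-cycle list downward and the immediate early list upward (adjusted p = 0.0322 each), and the block called 5 cell-cycle genes lower. None of the 6 immediate early genes passed over all probes, and 2 were higher over the list alone. Camera did not call the immediate early list with the preset (adjusted p = 0.0930) or the estimated correlation (0.480). The steroidogenesis list was called downward and the endothelial list upward with the preset correlation (adjusted p = 0.0433 each), and both were lost with the estimated one (adjusted p = 0.705 each). The endothelial list has 5 measured genes, none of them called, and Robo4 had the smallest p, at 0.52 ± 0.10. Adjusted over the list alone, and likewise with the block, 1 endothelial gene was higher and 0 lower. Lhcgr (0.07 ± 0.05), Star (0.05 ± 0.08), Cyp11a1 (0.10 ± 1.05) and Esr1 (0.03 ± 0.04) did not pass.

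Whether the reversal held outside the arrays used to find it was measured by calling activin-responsive probes in 3 experiments and reading them in the remaining one. In the experiment left out, these probes moved by 0.682 ± 0.090 (SD, n = 4 experiments) with activin in the called direction and by -0.257 ± 0.038 with activin plus follistatin, a share of -0.386 ± 0.110. The share lay between -0.551 and -0.323 in the 4 experiments, and 82.5% ± 4.1 of the probes were on the other side of PBS. With 4 experiments an exact sign-flip test cannot give a two-sided p below 0.125. Of the probes called in both comparisons against PBS, 66 had opposite directions and 1 the same, and with the block 382 and 13. Independent lists of these sizes would share 1.24 with opposite directions. With the PBS arrays split between the comparisons, 11 to 29 probes were opposite and 0 the same. Across the 14707 probes above background the differences had r = -0.59, where shared PBS arrays alone gave 0.50, and a covariance of -0.0312 against 0.00385. This correlation is across probes, which are not independent replicates.

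**Figure D2:**
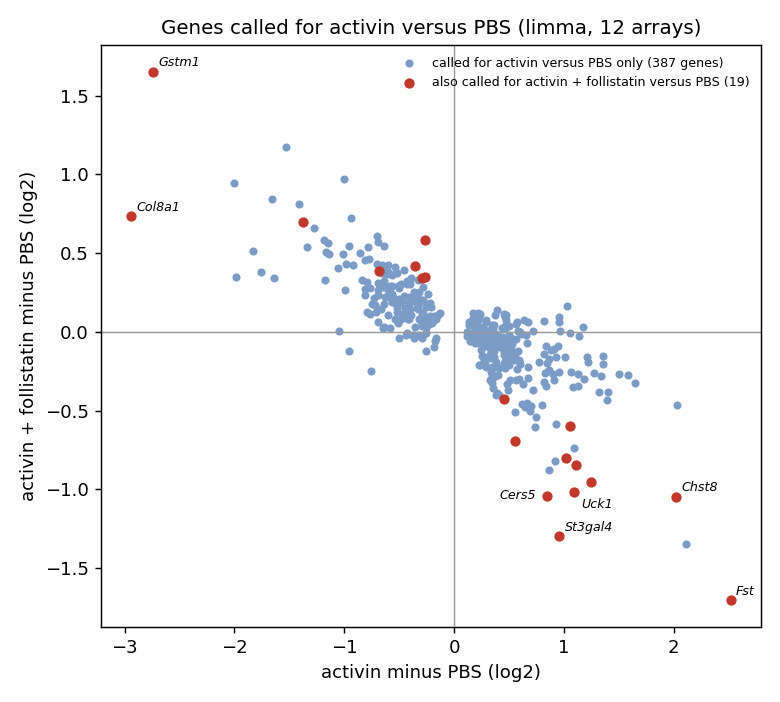
Difference of activin plus follistatin from PBS (y axis, log2) against that of activin from PBS (x axis, log2) for the 406 named genes called for activin versus PBS; red points are the 19 genes also called for activin plus follistatin versus PBS. All 19 red points have opposite signs on the axes, and both axes use the same PBS arrays.

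The call counts of activin plus follistatin versus PBS moved with single arrays, from 47 to 107 probes. The lowest, 47, came without the PBS array of experiment 2 or the activin plus follistatin array of experiment 3, and 48 and 50 probes came without the PBS array of experiment 3 and the activin plus follistatin array of experiment 1. The calls of Slit2, Tuba8, Igf1, C1s1, Gstm1 and Col8a1 were each lost when any 1 of 4 to 10 single arrays was left out, with adjusted p up to 0.163, although their directions held. Leaving out 1 whole experiment ended, for at least 1 experiment, the call of each gene named as changed here except St3gal4: that of Fst ended without experiment 3 (adjusted p = 0.0884) or 4 (0.0549).

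The comparison of activin with activin plus follistatin asks which effects of activin depend on free activin. It gave the largest differences of the study. Where activin plus follistatin lay on the other side of PBS, the difference adds that shift to the change with activin. Fst was higher by 4.22 ± 0.19 with activin alone, 18.6-fold, and Cables1 by 3.46 ± 0.43, Chst8 by 3.07 ± 0.12, Fam13a by 2.50 ± 0.15, St3gal4 by 2.26 ± 0.09, Igf1 by 2.20 ± 0.16, Uck1 by 2.11 ± 0.11 and Loxl1 by 1.97 ± 0.19. Gstm1 was lowest relative to activin plus follistatin (-4.39 ± 0.23), followed by Col8a1 (-3.67 ± 0.10), Cntnap2 (-2.95 ± 0.21), Dcn (-2.81 ± 0.54), Gstm2 (-2.70 ± 0.23), Gask1b (-2.50 ± 0.30), Aldh1a1 (-2.35 ± 0.22) and Cav1 (-2.34 ± 0.25). All 16, again picked only with the same direction in each of the 4 experiments, had adjusted p of at most 0.00662 (limma, Benjamini-Hochberg).

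The cell-cycle list held the most called genes of the fixed lists. Of its 21 measured members, 15 were higher with activin than with activin plus follistatin and none lower, and 17 were higher when p was adjusted over the list alone. They span DNA replication and mitosis: Cdc6 (0.78 ± 0.08), Rrm2 (0.69 ± 0.09) and Tk1 (0.63 ± 0.09) act in DNA synthesis, and Ccnb1 (1.07 ± 0.12) drives entry into mitosis. The median of the list was 0.67. Against PBS the mean of the list differed by 0.244 with activin and by -0.294 with activin plus follistatin. Camera called it with the preset correlation (adjusted p = 2.48e-10), not with an estimated correlation (adjusted p = 0.347), and fry gave an adjusted p of 3.92e-04. Fry also passed upward for the granulosa list (2.28e-05), with a mean of 0.82 and a median of 0.34 over 6 measured members that include Fst. It passed upward for the steroidogenesis (0.0200, mean 0.45, median 0.06) and Notch lists (0.0200, mean 0.06, median -0.003). Downward it passed for the stromal and theca (0.00346), immediate early (0.00596), glutathione (0.00713) and protease lists (0.0345), with medians of -0.05, -0.11, -0.03 and -0.01. Cdkn1a, an inhibitor of the cycle, was also higher (1.04 ± 0.20), and Ccnd1, a G1 cyclin with a signal near background, was lower (-0.19 ± 0.04).

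**Figure D3:**
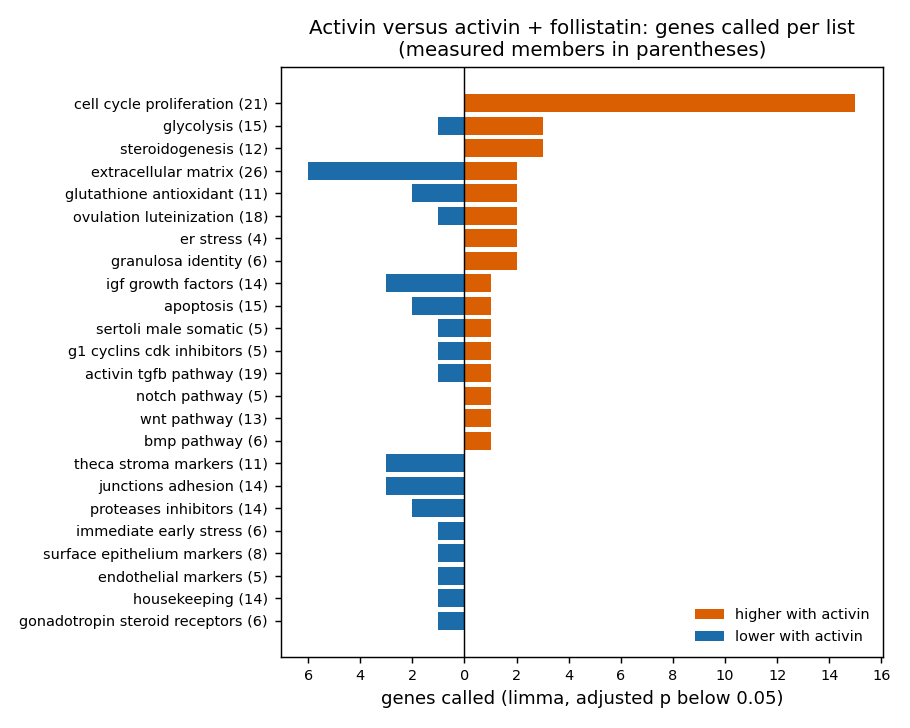
Number of genes per fixed list (x axis) called higher (right, orange) or lower (left, blue) with activin than with activin plus follistatin by limma; measured members in parentheses, and lists with no call are left out. The cell-cycle list holds 15 genes, all higher with activin, and the extracellular matrix list 2 higher and 6 lower.

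Of 26 matrix genes, 6 were lower with activin, among them Dcn, Col5a1 (-1.26 ± 0.15) and Col3a1 (-0.95 ± 0.12), while Loxl1 and Fbln1 (1.74 ± 0.20), a fibulin, were higher. Adjusted over the list alone, 7 were lower and 4 higher. Of 14 junction and adhesion genes, 3 were lower and none higher: plakoglobin Jup (-0.91 ± 0.09), alpha-catenin Ctnna1 (-0.72 ± 0.10) and N-cadherin Cdh2 (-0.63 ± 0.10). Adjusted over the list alone, and likewise with the experiment as a block, 5 junction genes were lower and 3 higher, and the median of the list was 0.03. Of 12 steroidogenesis genes, 3 were higher: Hsd11b2 (1.96 ± 0.09), Cyp1b1 (1.74 ± 0.22) and Scarb1 (1.44 ± 0.39), a receptor for high-density lipoprotein, and adjusted over the list alone 3 were higher and 1 lower. Of 15 glycolysis genes, the enolase Eno1 (1.49 ± 0.31), Pfkfb3 (1.27 ± 0.20) and the phosphofructokinase Pfkl (1.13 ± 0.26) were higher, and Pfkm (-0.95 ± 0.11), the muscle form of that enzyme, was lower, with 5 higher and 1 lower when adjusted over the list alone. Among 14 insulin-like and other growth factor genes, Igf1 was higher and 3 were lower, including Pdgfc (-0.72 ± 0.10) and Igfbp5 (-1.15 ± 0.30), a binding protein for insulin-like growth factors, and adjusted over the list alone 1 was higher and 5 lower. Apart from the cell-cycle list, camera called no list in this comparison. The cholesterol synthesis, interferon, oocyte, macrophage, smooth muscle and erythroid lists held 0 genes called by limma in any of the 3 comparisons, which had 5644, 3304 and 7456 probes at an unadjusted p below 0.05. The experiment block changed this for cholesterol synthesis, with 3 genes higher for activin versus PBS, 2 lower for activin plus follistatin versus PBS and 5 higher for activin versus activin plus follistatin, and for the interferon list, with 1 higher in the first and 1 lower in the last.

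Of 6 granulosa genes, Fst and Bex4 (0.74 ± 0.13) were higher with activin, and Wt1, a transcription factor of granulosa and other ovarian cells, had -0.73 ± 0.22 (adjusted p = 0.0792) and was lower in all 4 experiments. Adjusted over the list alone, and likewise with the block, 3 granulosa genes were higher and 1 lower. The prolactin receptor Prlr was lower (-1.59 ± 0.35), while Lhcgr (-0.03 ± 0.05), Star (0.06 ± 0.08), Cyp11a1 (-0.14 ± 1.05) and Esr1 (-0.04 ± 0.04) did not pass. Beside the matrix genes, 3 of 11 stromal and theca markers were lower, Aldh1a1, Col3a1 and Dcn (4 lower and 1 higher over the list alone), and 1 of 5 endothelial markers, Robo4 (-0.80 ± 0.10), and 1 of 8 surface epithelium markers, Gpm6a (-0.80 ± 0.17; 2 lower over the list alone). In total 3296 probes passed, 1682 up and 1614 down, and 969 named genes, 447 up and 522 down. With the experiment as a block the counts were 5087 probes and 1533 genes.

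Of the 406 named genes called for activin versus PBS, 390 were called in the same direction here. The activin arrays enter both comparisons, so the overlap was also read in other ways. Independent lists of these sizes would share 23.9 genes in the same direction, and with the activin arrays split between the comparisons 183 to 235 genes were shared. The covariance of the differences over the 14707 probes above background was 0.117, against 0.00384 from shared arrays alone. Leaving out 1 single array ended the call of Scarb1 for 11 of the 12 arrays, of Igfbp5 for 9 and of Pfkl for 3. Their adjusted p then reached up to 0.135 (limma). The calls of Dcn, Prlr, Eno1, Cdkn1a, Gpm6a and Ccnd1 were lost without at least 1 whole experiment, that of Ccnd1 also with the mean of its probes. Of the 20 probes with the largest rise 17 had no name here, and of the 20 with the largest fall 13, so the named genes are part of the response.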

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

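The random lists matched on signal and the regroupings of arrays were planned before the results were seen, and the other tests in this part were chosen only after the result they measure had been seen. Of 267 groups of 4 arrays, for 89 genes in 3 treatments, 10 had 1 array that stood far from the other 3, where chance gives about 1 in 20. In the PBS cultures these were Gclm in experiment 1, at 9.26 where the others lay at 8.80 to 8.86, and Pfkm in experiment 2, at 9.90 with the others at 10.4. With activin they were Bcl2 in experiment 3 (7.37, others 7.29 to 7.30), Gask1b in experiment 4 (10.2, others 10.7 to 10.8), Slc18a2, which encodes a vesicular monoamine transporter, in experiment 2 (7.65, others 8.72 to 8.92), and Socs2 in experiment 4 (12.6, others up to 13.1). With follistatin added they were Hsd11b2 in experiment 4 (7.15, others 7.27 to 7.28), Slc18a2 in experiment 1 (8.25, others 7.25 to 7.32), Tnfrsf10b in experiment 3 (7.37, others 7.29 to 7.30) and Tuba8 in experiment 1 (7.41, others 7.85 to 7.87). Experiments 1 to 4 held 3, 2, 2 and 3 of them. The value of Slc18a2 in both arrays lay toward the level of the other treatment, in arrays of different experiments, while Fst kept to its group in all arrays, at 12.9 ± 0.20 (SD, n = 4) with activin and 8.70 ± 0.35 with follistatin added.

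The first pattern weighed is that genes changed by activin lay on the other side of PBS with follistatin added. Noise in the shared PBS arrays moves both differences from PBS the same way, with r = 0.50 in simulated unchanged groups, which is the reverse of this pattern. With the PBS arrays split between the comparisons, as given in the Results, 11 to 29 probes were opposite and 0 the same. These values argue against noise in the shared PBS arrays for the called probes. A difference in scaling between arrays would move rising and falling probes the same way, and their difference in the experiments left out was -0.518 ± 0.0778 (SD, n = 4), with -0.24 for rising and 0.27 for falling probes. A candidate explanation is that activin or related ligands made by the cells act in the PBS cultures and are also blocked by follistatin: 80.5% of the 82 probes called between activin plus follistatin and PBS were called in the opposite direction for activin. This cannot be told apart from another effect of follistatin, because the design has no cultures with follistatin alone.

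The second pattern is that cell-cycle genes were higher with activin than with activin plus follistatin. Differences between experiments that shift all treatments alike cancel here by design, because each experiment supplied 1 array of each treatment. Within the 4 experiments the mean of the list differed by 0.538 ± 0.171 (SD), from 0.365 to 0.773. Against PBS this mean differed by 0.244 ± 0.175 (SD) with activin and by -0.294 ± 0.0353 with activin plus follistatin. The pattern is therefore not a rise with activin alone. A shift of all genes at this signal level does not account for the pattern. The median of the list, 0.67, was at percentile 100 of 10000 random lists matched on signal, of which the highest reached 0.18. The camera call was lost with an estimated correlation, which shows that the members vary together. A treatment effect on proliferation may underlie the pattern, as a hypothesis that expression alone does not test.

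The third pattern is that Aldh1a1 and Col3a1, 2 of 11 stromal and theca markers, were lower with activin than with PBS; camera did not call the list (adjusted p = 0.256). If the activin cultures held fewer such cells, all their markers would be lower by similar amounts. The 3 markers clearly above background differed by up to 1.10 between one another, with Aldh1a1 at -1.83 ± 0.22, Dcn at -1.77 ± 0.54, which did not pass the test, and Col3a1 at -0.73 ± 0.12. Gli2 went the other way (0.20 ± 0.10, called higher with experiment as a block) from 7.42, close to background. With no sort of the cells in the labels, fewer stromal or theca cells and a change of these genes within granulosa cells cannot be told apart here, because signals near background compress the change of Col3a1, which was at 7.89 with activin, and because the other markers, apart from Wt1, which granulosa cells also express, lie near background.

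For the counts of called probes, of 35 splits of the 8 arrays 1, the real one, gave as many in each of the 3 comparisons. This does not exclude chance, because the experiments pair the arrays and these splits ignore the pairing. Other splits also keep treatment differences within their groups, which widens the spread and lowers their counts. Activin versus PBS gave 1342 probes and the highest other split 0, and activin versus activin plus follistatin gave 3296 and the highest other split 0. Activin plus follistatin versus PBS gave 82, and the highest other split gave 48. That split sets both arrays of experiments 1 and 3 against those of experiments 2 and 4, and so follows differences between experiments; with experiment as a block the real count was 557. The numbers pair the samples, and among the 8 splits that part all 4 pairs the highest other count was 0 in each comparison, though 8 splits are too few for a share below 0.05. For the counts of called gene lists over all splits chance cannot be excluded: 13, 11 and 28 of the 35 splits gave as many lists as the real 3, 3 and 1 for activin versus PBS, activin plus follistatin versus PBS and activin versus activin plus follistatin, and the highest other splits gave 6, 6 and 7. Among the 8 splits that part all pairs, 2, 1 and 6 gave as many lists, with highest others of 3, 2 and 4.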

How the results depend on the processing

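The alternatives in this part were planned, and the summaries of which array ended a call were chosen after the results were seen. Over 28 alternatives, 208 results for single genes gave 5804 values. Of these 5274 stayed on their side of the threshold, 431 were weaker, 99 were stronger and 0 reversed. The 5274 include genes called in neither fit. With the stricter p and fold thresholds left aside, 108 of the 208 results were the same under every alternative. The sign of a gene called neither in the main fit nor in the alternative was not compared. Results of gene lists were the same in 602 cases, weaker in 24, stronger in 7 and reversed in 0. For lists, a reversal was counted only where both fits called the list. With experiment as a block, 166 gene results were the same and 42 stronger.

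For activin versus PBS, 1342 probes became 2820 with the block, 597 at an adjusted p below 0.01 and 479 with at least a 1.5-fold change, and leaving out arrays or experiments gave 625 to 1356. For activin plus follistatin versus PBS, 82 probes became 557 with the block, 132 with a random block, 127 with only the 8 arrays compared, 131 among probes above the 75th percentile of signal, 34 at an adjusted p below 0.01 and 47 with at least a 1.5-fold change, and leaving out gave 24 to 107. For activin versus activin plus follistatin, 3296 probes became 5087 with the block, 1945 at an adjusted p below 0.01 and 1216 with at least a 1.5-fold change, and leaving out gave 2091 to 3268. The block takes out differences between experiments, stricter thresholds lower counts by construction, and fewer probes tested ease the adjustment; for the random block, the fit of 8 arrays and the arrays or experiments left out the cause was not tested. Quantile normalization gave 1337, 95 and 3293 probes.

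The share of the activin change left with follistatin stayed between -0.407 and -0.332 without single experiments and was -0.382 after quantile normalization. The 390 genes shared by both activin comparisons became 800 with the block, 183 to 235 with the activin arrays split and 186 to 261 without single experiments. Camera called 3, 3 and 1 lists in the 3 comparisons, 0 in each with an estimated correlation, 3 for activin versus activin plus follistatin with the block, and 1 and 1 in the comparisons against PBS among probes above the 50th percentile. Leaving out whole experiments gave 1 to 4, 1 to 3 and 1 to 2 lists, and the lists were not tested without single arrays. For the block and the filter the cause was not tested. Of the probes tested, 31.9% had a signal over background, which limits what can be seen of the rest.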

Other observations

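The values in this part were chosen after they were seen and belong to no planned comparison. Of 4071 named genes above background, 2284 (56.1%) had a larger range over the 4 experiment means than over the 3 treatment means. Noise alone gives on average a wider range over 4 means of 3 arrays than over 3 means of 4 arrays. The share therefore does not show that experiment outweighed treatment. A range of at least 2 log2 units was seen for 4 genes over experiments and 19 over treatments. The 4 genes were Cyp11a1, with experiment means of 13.6, 12.5, 14.5 and 10.7, Sfrp4, a secreted Wnt antagonist (range 2.60), the potassium channel Kcnk2 (2.35) and Tmem14c (2.11).

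Some lists had a larger range over experiments than over treatments, and others a smaller one. Here too, noise alone widens the range over experiments more than that over treatments. The cell-cycle list had a range of 0.20 over experiments against 0.71 over treatments, and the stromal and theca list 0.35 against 1.09. The mean of 10 cholesterol synthesis genes above background was 10.9, 10.1, 10.9 and 9.85 in experiments 1 to 4, a range of 1.06 against 0.46 over treatments, and that of 9 steroidogenesis genes was 10.1, 9.82, 10.3 and 9.44. The mean of 7 interferon response genes was 8.37 in experiment 1 and 7.80, 7.80 and 7.76 in the others. In experiment 1 the oocyte genes Omt2a (8.93 against 7.16 to 7.21) and Obox5 (8.73 against 7.21 to 7.28) were above background in that experiment alone. No explanation of these differences was tested.

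Of the 20 probes with the largest rise and the 20 with the largest fall, 16 and 13 had no gene name in activin versus PBS, 13 and 18 in activin plus follistatin versus PBS, and 17 and 13 in activin versus activin plus follistatin. The unnamed probe with the largest rise reached 4.24, 1.77 and 5.49 in the 3 comparisons, and that with the largest fall -3.57, -2.63 and -4.06.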
